A study of Mus musculus with 29 samples.

How the data were processed

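RNA was measured in cultures of primary cortical neurons from adult C57/BL6 mice, per the labels, with an ultra-low input library kit and sequencing on a HiSeq4000, per the labels' protocols. The 29 libraries were grouped by treatment (conditioning lesion or naive) and day in culture (1, 2, 3, 5 or 7), taken from their titles. The labels do not say whether the libraries of a group came from separate cultures or animals. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Reads were aligned with STAR to the mouse genome build mm10, per the submitters' processing notes. The counting tool, the filter on low counts and the scaling are not given in the sources used here, and neither is whether counting used strand.

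The file used is 1 table of the authors' own comparisons, lesion against naive at each of the 5 days, made with voom and limma and kept at a false discovery rate under 0.1, per the name of the deposited file. Its values are log2 fold changes, p-values and adjusted p-values computed by the authors, per the file headers. The largest of the genes' smallest adjusted p-values was 0.09997, so each gene passes at 1 or more days. Adjusted p-values of the deposited table are those of Benjamini and Hochberg within each day: rebuilding them for 19085 tests returned the deposited values to a relative deviation of at most 9.15e-13. A column of ranks has no unit and no explanation in the deposited file; abundant genes have low numbers, and it is read here as the rank of mean expression with 1 the highest. No per-sample values were used, and no counts per library, so the depth per sample and the precision it gives are unknown here. With 2 or 3 libraries per group, a fold change of a weakly expressed gene can rest on very few reads, and its size should be read with its standard error.

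As the table gives only comparisons, no per-gene test was fitted again and genes were counted at the authors' adjusted p under 0.1, a form of the design that was fixed before the data were examined together with the 39 gene lists, the rule for named genes and a set of other thresholds and settings. Standard errors were implied by each fold change and its p-value from the t distribution. The degrees of freedom, 37, were those at which the implied error depended least on the size of p among the most expressed genes (rank up to 4771); a fit of 10 group means to 29 libraries alone leaves 19. The design allowed a test between days only with standard errors or t values per day; the table gives neither, and the implied ones stand in their place. That test is Cochran's heterogeneity over the 5 days as an F test, and pairs of days were compared with a t statistic from the same errors. Both were adjusted over 19085 genes with the genes outside the table set to a p of 1, so their counts are lower bounds.

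Each list was tested at each day with 3 or more changed members, 83 list and day pairs in all, by a two-sided Fisher's exact test of direction: risen against fallen members, compared with the other changed genes of the day, adjusted over the 83 pairs at a threshold of 0.05. Of these, 17 passed. All tests of lists and gene families count genes as independent, though members can move together in the same libraries. Their p-values therefore do not measure the spread between libraries or cultures. Counts adjusted over the list alone set list genes outside the table to a p of 1. Symbols were matched through synonyms for 9 list genes. Alternatives chosen after seeing the data were a direction test matched on 10 bins of expression rank (exact, two-sided), over-representation among risen or fallen genes against all genes tested (390 tests, list genes outside the table counted as tested and unchanged), and a restriction to genes with a rank up to 9542. Overlaps between days were tested with Fisher's exact test over 19085 genes and adjusted over 40 tests; intervals of correlations come from 1000 bootstrap draws of genes. Differences in direction between 2 days were tested for 67 list and day-pair combinations.

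Named genes are those with the 6 highest and 6 lowest log2 fold changes past the threshold at each day (predicted genes and those with a rank above 14313 left out), up to 4 members with the smallest adjusted p of each list that passed its direction test, up to 10 genes past the threshold in the same direction at the most days, and 16 genes fixed in advance, of which 10 are in the table. The rule gave 129 genes. Further list members named as examples, such as Il1b, Cd14, Csf1r, Mag, Cldn5, Flt1, Kdr, Slco1a4, Mki67, Hspa1a, Hspa1b, Gja1, Sema3a, Epha4, Ephb1 and Nrp1, were chosen after their values were seen. Some genes that the rule or the lists gave are not reported here by name, though counts include them.

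Gene positions and types, exonic lengths and GC contents came from GENCODE vM21 (GRCm38, the same assembly as mm10); of 5442 symbols with a chromosome in the table, 5439 had the same chromosome and strand there. The recovery of the number of tests and of the errors, the test between days and the direction tests were tried on simulated data, 19085 genes in the 29 libraries, fitted with limma 3.58.1 in R 4.3.3. The number of tests was recovered exactly, and the degrees of freedom as 24 against 23.95. Of genes changed 4-fold at day 5 only, 97.1% were called at day 5 and 88.5% differed between days. Of genes changed alike at all days, 1.67% were called as differing, and 4.38% of all such calls were false. Random lists passed the direction test at an unadjusted p under 0.05 in 5.0% of cases. Lists of weakly expressed genes, simulated with a rank trend, did so in 55.3% of cases without and 3.67% with rank matching. Noise was simulated independently for each gene, and the random lists were drawn from the changed genes. The rate of 5.0% was therefore nearly fixed in advance. These rates do not cover lists whose members move together. Other work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.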

Results

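Gene expression was measured by RNA sequencing in cultures of cortical neurons prepared from adult C57/BL6 mice. In the lesion groups the animals had received a conditioning lesion, an injury made in the living animal a day before the neurons were plated; naive groups received none. Cultures were harvested at days 1, 2, 3, 5 and 7, which gave 10 groups and 29 libraries, 15 lesion and 14 naive. Each group held 3 libraries except the naive group of day 7, which held 2. The table used here gives, for each day, the authors' log2 fold change of lesion against naive, its p-value and its adjusted p-value, for 5826 genes past an adjusted p of 0.1 at 1 or more days. The adjusted p-values correspond to 19085 genes tested at each day, so the table holds 30.5% of them. It holds no value per library, and the depth of the libraries is unknown here. Positive fold changes mean higher in lesion cultures, and "rose" and "fell" are used below only for an adjusted p under 0.1. The standard errors given with fold changes are those implied by each fold change and its p-value.

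The comparisons address how a conditioning lesion of the central nervous system alters gene expression in adult cortical cultures over time. Numbers of genes changed differed widely between days. At day 1, 118 genes changed in the authors' deposited table (17 rose, 101 fell), with 1140 at day 2 (361 rose, 779 fell) and 282 at day 3 (102 rose, 180 fell). The balance at day 3 depended on expression, as 98 genes rose and 56 fell among those with a rank up to 9542. At day 5 the count was 4575 (2438 rose, 2137 fell), which is 24.0% of the genes tested, and at day 7 it was 781 (593 rose, 188 fell). The balance at day 5 also depended on expression, as 947 genes rose and 1906 fell among those with a rank up to 9542.

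**Figure D1:**
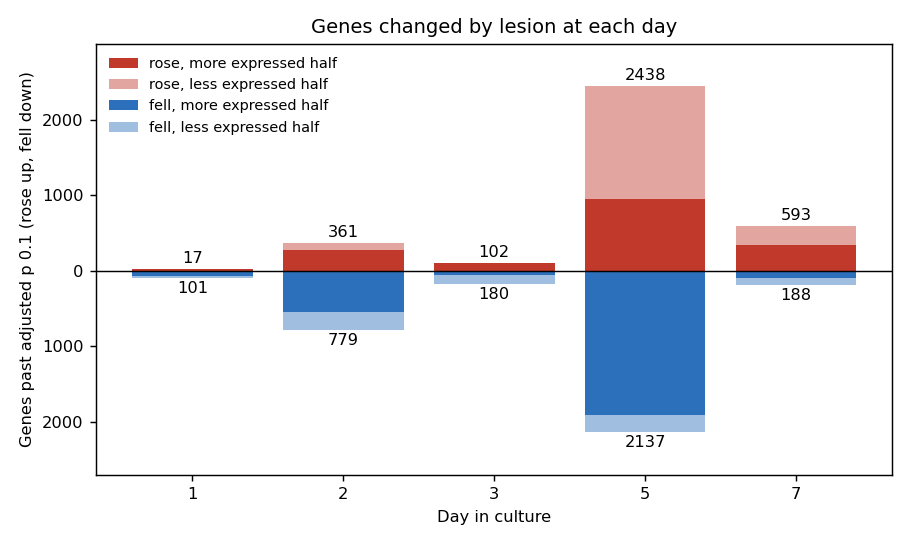
Number of genes that rose (red, upward) or fell (blue, downward) in lesion against naive cultures at each day, at an adjusted p under 0.1 in the authors' table. Dark segments are genes with an expression rank up to 9542 of 19085, pale segments the less expressed genes; at day 5, 1491 of the 2438 risen genes are pale and 1906 of the 2137 fallen genes are dark.

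At day 1, lesion cultures had lower levels of inflammatory genes and higher levels of a few neuronal genes, among them growth-cone and cytoskeletal ones. Of 34 cytokine and chemokine genes 8 fell and none rose (10 fell when adjusted over the list alone), against 0.18 expected from all genes tested. The chemokine genes Ccl4 (fell by 3.70, implied standard error 0.55), Ccl5 (fell by 3.70, standard error 0.62) and Cxcl2 (fell by 3.94, standard error 0.75) were among the 6 lowest log2 fold changes of genes with a rank up to 14313 in the authors' deposited table. Il1b, the gene of interleukin 1 beta, fell by 3.85 in the authors' deposited table, with an adjusted p of 0.0468. Among 30 microglia and macrophage markers 3 fell (4 adjusted over the list alone), among them Cd14 (log2 fold change -3.32) and Csf1r (-2.26), the receptor for a macrophage growth factor, in the authors' deposited table. Interferon-stimulated genes gave 4 of 31 fallen (7 adjusted over the list alone), with Oasl1 at -3.62 and Ifit3 at -3.97 in the authors' deposited table. Of 26 immediate early genes 4 fell (5 adjusted over the list alone), including Atf3, an injury-induced transcription factor, which fell by 2.06 in the authors' deposited table (adjusted p = 0.0462). 

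Other neuronal lists also had risen members at day 1 when adjusted over the list alone, so a rise was not particular to growth genes. Pan-neuronal markers and synaptic genes each gave 5 risen and none fallen, and axon guidance genes 6 risen and 1 fallen. Glutamatergic cortical neuron markers and ion channel genes gave none. Growth-cone and cytoskeletal genes moved against the inflammatory genes: 3 of 40 rose and none fell (8 rose and 2 fell when adjusted over the list alone). They were the microtubule-associated genes Map1b (1.10, standard error 0.25) and Dcx (1.02, standard error 0.25) and the growth-cone gene Dpysl2 (0.91, standard error 0.24), in log2 units of the authors' deposited table. Gria2, a subunit of AMPA-type glutamate receptors, rose by 1.63 in the authors' deposited table (adjusted p = 0.0287). Fisher's exact test of direction, which sets the share of rising genes among changed list members against that among the other changed genes of the day, gave an adjusted p of 0.0151 for the cytoskeletal list and 0.779 for cytokines, as 101 of all 118 changed genes fell. Set against all genes tested, the fallen cytokine genes were over-represented (Fisher's exact test, adjusted p = 4.89e-10). Here and at later days, such tests count genes as independent, though members of a list can move together in the same libraries. Small p-values of lists thus do not measure replication over cultures. With direction matched on expression rank, the cytoskeletal list had an adjusted p of 0.135.

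By day 2, markers of oligodendrocytes and of endothelial cells were lower in lesion cultures, while mitochondrial respiratory and ribosomal protein genes were higher. All 10 oligodendrocyte markers in the table, of 24 on the list, fell (10 adjusted over the list alone). Olig2, a transcription factor of the oligodendrocyte lineage, fell by 8.29 (standard error 1.38, adjusted p = 0.000899) in the authors' deposited table, and the myelin gene Mag fell by 2.66. Of 20 endothelial markers 9 fell and none rose (15 fell when adjusted over the list alone), including the tight junction gene Cldn5 (-2.22) and the vascular growth factor receptors Kdr (-2.99) and Flt1 (-2.73) of the authors' deposited table. Oxidative phosphorylation genes gave 12 risen of 36 and none fallen (17 risen when adjusted over the list alone), with Cox5b at 0.64 (standard error 0.17) and Ndufa2 at 0.75 (standard error 0.16) in the authors' deposited table. Ribosomal protein genes of the cytosol gave 6 risen of 45 (7 adjusted over the list alone), for example Rps19, which rose by 0.74 in the authors' deposited table. 

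Antioxidant genes of the oxidative stress list rose in 5 of 22 cases at day 2 with none fallen (5 adjusted over the list alone), among them Nqo1 (1.61, standard error 0.45), a quinone reductase, and Gpx4 (0.85, standard error 0.19), a lipid peroxide reductase, in the authors' deposited table. Of 40 cytoskeletal and growth-cone genes 13 fell and none rose (17 fell when adjusted over the list alone), including Map1b (-0.82), Dpysl2 (-1.13) and the neuronal tubulin gene Tubb3 (-1.18) of the authors' deposited table. Cell cycle genes gave 7 fallen of 30 (14 adjusted over the list alone), with the proliferation marker Mki67 at -2.63 in the authors' deposited table. Cholesterol biosynthesis gave 6 fallen of 22 (7 adjusted over the list alone). Sox11, a developmental transcription factor that is linked to axon growth, fell by 1.32 (adjusted p = 0.0108), and Jun, a regeneration-associated transcription factor, fell by 1.24 (adjusted p = 0.0563), per the authors' deposited table. 

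Direction tests at day 2 passed for oxidative phosphorylation (adjusted p = 2.48e-05, Fisher's exact test), ribosomal proteins (0.00734) and oxidative stress (0.0173). Oligodendrocyte markers (adjusted p = 0.136), endothelial markers (0.174) and the cytoskeletal list (0.0583) missed that threshold; their fallen members were over-represented against all genes tested, with adjusted p-values of 4.59e-07, 9.37e-07 and 1.67e-07. With direction matched on expression rank, the adjusted p was 0.128 for the oxidative stress list, 0.00621 for the cytoskeletal list and 0.308 for both oligodendrocyte and endothelial markers. Cell cycle (adjusted p = 0.256) and cholesterol biosynthesis genes (0.394) also missed the direction test, with 0.39 and 0.319 when matched on rank. Their fallen members were over-represented against all genes tested (Fisher's exact test, adjusted p = 0.00214 and 0.00235).

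Several day 2 changes were also present at day 3, where fewer genes passed the threshold. Olig2 fell by 7.97 (standard error 1.39) at day 3 in the authors' deposited table, and Lmo1, which encodes a LIM-domain regulator of transcription, fell by 6.27 (standard error 1.02). Endothelial markers fell in 5 of 20 cases with none risen (16 fell when adjusted over the list alone), among them Slco1a4 at -3.74, a transporter of brain vessels, in the authors' deposited table. Of 20 GABAergic neuron markers 3 rose (8 rose and 1 fell when adjusted over the list alone), among them the GABA-synthesis genes Gad1 (1.21, standard error 0.29) and Gad2 (1.23, standard error 0.33) of the authors' deposited table. Gria2 again rose, by 1.46 (adjusted p = 0.00806 in the authors' deposited table). Heat shock genes gave 3 fallen of 18 (2 rose and 6 fell when adjusted over the list alone), with the inducible chaperones Hspa1a at -3.56 and Hspa1b at -3.94 in the authors' deposited table; these are near-identical copies, so reads could be split between them. No list passed the direction test at day 3. Against all genes tested, over-representation had an adjusted p of 2.11e-05 for fallen endothelial markers, 0.00213 for risen GABAergic markers and 0.00623 for fallen heat shock genes.

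At day 5, extracellular matrix, mesenchymal, cell cycle, reactive astrocyte and antioxidant genes were higher in lesion cultures, and pan-neuronal, GABAergic, synaptic and respiratory genes were lower. Of 40 extracellular matrix and adhesion genes 26 rose and 1 fell (28 rose and 1 fell when adjusted over the list alone). Col1a1, a fibrillar collagen, rose by 5.53 (standard error 0.61, adjusted p = 1.23e-07), and Timp1, an inhibitor of matrix metalloproteinases, rose by 4.81 (standard error 0.45, adjusted p = 6.52e-09), in the authors' deposited table. Col3a1 had the highest log2 fold change among the genes named by rule, 11.14 with a standard error of 2.36 in the authors' deposited table. Mural, fibroblast and meningeal markers gave 14 risen of 20 and none fallen (15 rose and 1 fell when adjusted over the list alone). Among them was the proteoglycan gene Cspg4, which is not particular to mural cells, at 4.27 in the authors' deposited table.

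Of 30 cell cycle genes 27 rose at day 5, with none fallen (27 adjusted over the list alone), among them Birc5 (3.84, standard error 0.69) and the replication gene Mcm5 (3.97, standard error 0.84) of the authors' deposited table. Reactive astrocyte genes gave 19 risen and 2 fallen of 36 (19 and 2 adjusted over the list alone), including Vim, an intermediate filament gene, at 2.56 (standard error 0.44) in the authors' deposited table. Of 20 astrocyte markers 9 rose and 1 fell (9 and 1 adjusted over the list alone), with the gap junction gene Gja1 at 5.59 and Gfap at 1.89 in the authors' deposited table. Oxidative stress genes gave 13 risen and 1 fallen of 22 (14 and 1 adjusted over the list alone); Nqo1 rose by 4.49 (standard error 0.39, adjusted p = 1.27e-09) and Prdx1 by 2.62 (standard error 0.42) in the authors' deposited table. Interferon-stimulated genes, 4 of which had fallen at day 1, gave 9 risen of 31 and none fallen (9 adjusted over the list alone), with Ifitm3 at 3.29 in the authors' deposited table.

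Several neuronal lists fell at day 5, but markers of glutamatergic cortical neurons showed no common direction. Of 38 synaptic genes 23 fell and none rose (23 adjusted over the list alone), including the vesicle genes Vamp2 (-1.36, standard error 0.24) and Sv2a (-1.38, standard error 0.26) and Gria2 (-1.71, standard error 0.30) of the authors' deposited table. Pan-neuronal markers gave 14 fallen of 24 and none risen (15 fallen when adjusted over the list alone), and GABAergic markers 15 fallen and 1 risen of 20 (15 and 1 adjusted over the list alone). Glutamatergic cortical neuron markers gave 2 risen and 3 fallen of 25 (2 and 3 adjusted over the list alone), with a direction test at an adjusted p of 0.819. Gad1 fell by 1.64 and Gad2 by 1.97 in the authors' deposited table. Ion channel genes gave 12 fallen and 1 risen of 30 (12 and 1 adjusted over the list alone), cytoskeletal and growth-cone genes 19 fallen and 4 risen of 40 (20 and 5 adjusted over the list alone). Gap43, a growth-cone protein gene of regenerating axons, fell by 1.29 (standard error 0.32, adjusted p = 0.00543), and Map2, a dendritic microtubule gene, fell by 1.70 (standard error 0.37), in the authors' deposited table. Oxidative phosphorylation genes gave 13 fallen of 36 and none risen (15 fallen when adjusted over the list alone), with Cox5b at -0.66 (standard error 0.16) in the authors' deposited table. 

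Of the regeneration-associated list 14 rose and 8 fell of 46 at day 5 (14 and 9 adjusted over the list alone). Of the genes fixed in advance, Klf4, a transcription factor that restrains axon growth, rose by 2.23 (adjusted p = 0.00464) in the authors' deposited table. Gal, a neuropeptide gene, had a log2 fold change of -1.69, Sox11 of -1.15 and the neuronal nuclear marker gene Rbfox3 of -1.07, each past the threshold at day 5 in the authors' deposited table. Atf3 (-0.68), Jun (0.29) and Tubb3 (-0.79) did not pass it at day 5 in the authors' deposited table. Sprr1a, Stat3, Klf6, Klf7, Socs3 and Aif1, also fixed in advance, are not among the 5826 genes.

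The direction test at day 5 gave adjusted p-values (Fisher's exact test) of 1.94e-06 for synaptic genes, 3.07e-06 for the cell cycle, 3.14e-05 for extracellular matrix, 0.000382 for pan-neuronal markers, 0.000684 for oxidative phosphorylation, 0.00164 for GABAergic and 0.00176 for mural, fibroblast and meningeal markers. It gave 0.00475 for both reactive astrocyte and cytoskeletal genes, 0.00734 for ion channels, 0.015 for oxidative stress and 0.0219 for interferon-stimulated genes, while astrocyte markers (0.0997) and regeneration-associated genes (0.618) missed 0.05. Risen members of these lists were over-represented against all genes tested, with 9 against 2.55 expected (adjusted p = 0.00443) and 14 against 5.88 (0.0125). Direction at day 5 followed the expression rank, with a median log2 fold change of -0.51 among the 526 listed genes ranked 1 to 1000 and of 3.78 among the 483 of the bin that starts at rank 15001. With direction matched on rank, cytoskeletal genes (adjusted p = 0.714), interferon-stimulated genes (0.134) and oxidative phosphorylation (0.0782) no longer passed, and the unfolded protein response list (13 risen, 3 fallen of 30; 13 and 3 adjusted over the list alone) passed at 0.000378 against 0.148 without matching, as did cytosolic ribosomal proteins (10 risen, 1 fallen of 45; 10 and 1 adjusted over the list alone) at 0.000466 against 0.059. Without genes that another list holds, the day 5 calls of reactive astrocyte and cytoskeletal genes (adjusted p = 0.0704 each), mural, fibroblast and meningeal markers (0.0729) and interferon-stimulated genes (0.053) were lost. Among genes with a rank up to 9542, ion channels (0.286) and cytoskeletal genes (0.298) did not pass, and interferon-stimulated genes had too few changed members to test. In that restriction regeneration-associated (0.0344), immediate early (0.0344), astrocyte (0.0328), endothelial (0.0391), unfolded protein response (0.00103) and ribosomal protein genes (0.00103) passed at day 5, which they did not among all changed genes.

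**Figure D2:**
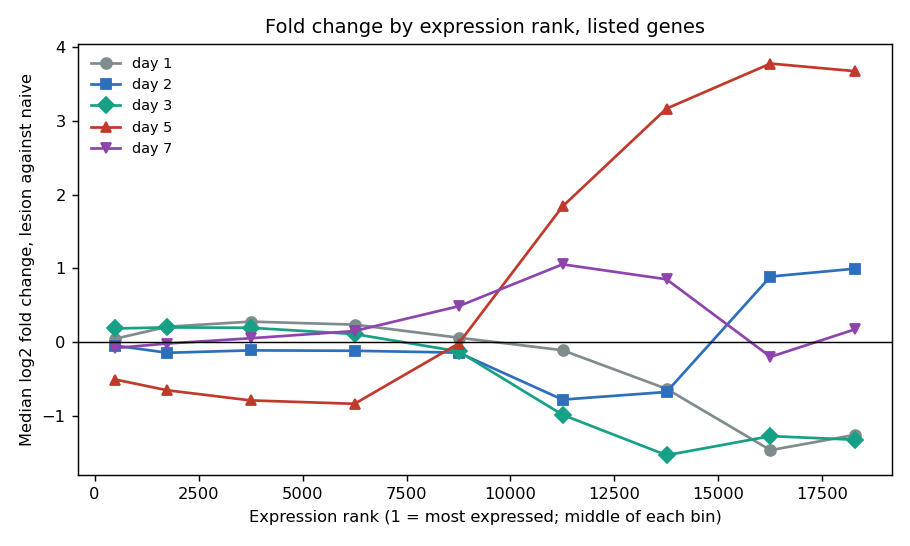
Median log2 fold change of lesion against naive cultures by expression rank (1 the most expressed) for the listed genes, 1 line per day. The day 5 line goes from -0.51 at ranks 1 to 1000 to 3.78 in the bin that starts at rank 15001, while the day 3 line goes from 0.19 to -1.28 over the same bins.

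**Figure D3:**
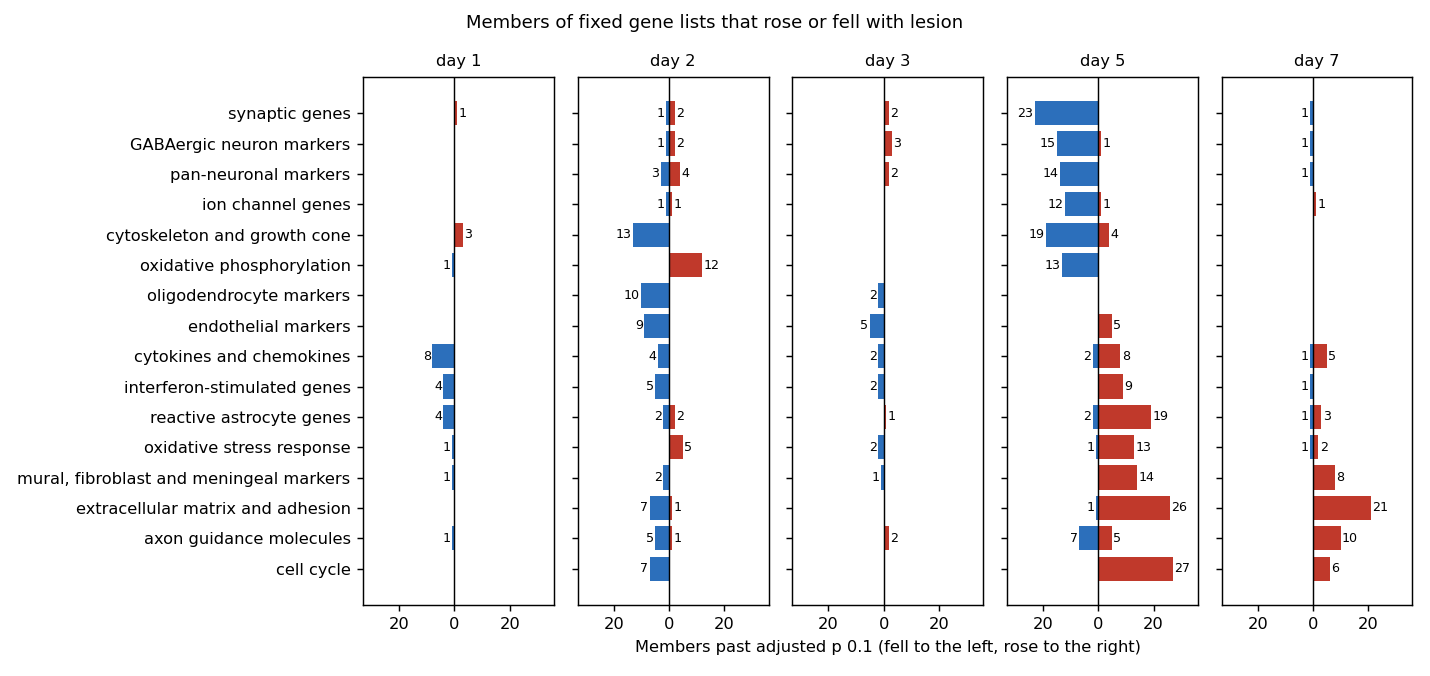
Members of 16 of the 39 fixed gene lists that rose (red, to the right) or fell (blue, to the left) in lesion cultures at each day; bar lengths and the numbers beside them are genes past an adjusted p of 0.1. At day 5 the cell cycle bar shows 27 risen and the synaptic bar 23 fallen, while oxidative phosphorylation shows 12 risen at day 2 and 13 fallen at day 5.

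Matrix genes were again higher at day 7, as were genes of axon guidance. Extracellular matrix and adhesion gave 21 risen of 40 and none fallen (22 adjusted over the list alone), with Col1a1 at 3.35 (standard error 0.36, adjusted p = 3.46e-07) and Mmp14, a membrane-bound matrix metalloproteinase, at 1.66 (standard error 0.22) in the authors' deposited table. Mural, fibroblast and meningeal markers gave 8 risen of 20 and none fallen (8 adjusted over the list alone), including the smooth muscle gene Tagln at 1.38 in the authors' deposited table. Of 37 axon guidance genes 10 rose and none fell (12 rose and 1 fell when adjusted over the list alone). They included the repellent Sema3a (5.08, standard error 1.54), its receptor Nrp1 (1.02, standard error 0.31) and the ephrin receptors Epha4 (3.77) and Ephb1 (4.11) of the authors' deposited table. Cell cycle genes gave 6 risen of 30 (21 adjusted over the list alone), with Birc5 at 1.85 and Tyms, which serves thymidylate synthesis, at 2.02 in the authors' deposited table.

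Among the highest fold changes of day 7 were Chil1 (8.30, standard error 1.80), a secreted chitinase-like protein, and Inhbb (7.08, standard error 1.28), an activin subunit, in the authors' deposited table. Grin2a, a subunit of NMDA-type glutamate receptors, was among the lowest with -5.09 (standard error 1.25), after it had risen by 3.89 at day 2, in the authors' deposited table. Gad1 fell by 1.01 and Gal by 2.16 at day 7 in the authors' deposited table. The direction test passed at day 7 for extracellular matrix (adjusted p = 0.0199, Fisher's exact test), but not for axon guidance (0.289) or mural, fibroblast and meningeal markers (0.435), as 593 of the 781 changed genes rose. Without genes that another list holds, extracellular matrix no longer passed at day 7 (adjusted p = 0.108). Over-representation against all genes tested gave adjusted p-values of 3.51e-19, 3.1e-06 and 1.95e-06 for these lists. Only 2 naive libraries stand behind this day.

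Genes past the threshold in the same direction at 2 or more days were few, 698 in all. Where the other day needed only an unadjusted p under 0.05, the number was 2211. Of the 5826 genes 4882 passed the threshold at 1 day only, 403 rose at 2 or more days, 301 fell at 2 or more days, and 350 rose at one day and fell at another. Timp1 and Nqo1 rose at days 2, 5 and 7, Gria2 rose at days 1, 2 and 3, and Map6d1, a microtubule-stabilising protein gene, fell at days 2, 3, 5 and 7, the single gene past the threshold in the same direction at 4 days. Days 2 and 3 shared 45 risen and 101 fallen genes, where independent lists would share 1.93 and 7.35 (Fisher's exact test, adjusted p = 1.79e-49 and 2.02e-91). Days 5 and 7 shared 336 risen and 65 fallen genes, against 75.8 and 21.1 (adjusted p = 3.27e-147 and 8.5e-17). Of the genes risen at day 3, 75 fell at day 5, against 11.4 for independent lists (adjusted p = 2.51e-48).

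Across the 5826 genes, which are not independent replicates, fold changes of days 2 and 3 correlated positively (Pearson r = 0.641, Spearman's rho = 0.526), as did those of days 5 and 7 (0.289 and 0.354). Day 5 correlated negatively with day 1 (r = -0.489, rho = -0.544) and day 3 (r = -0.464, rho = -0.555), and near 0 with day 2 (r = 0.0287). With the trend along expression rank taken out, the values for days 1 and 3 were smaller in size (r = -0.295 and -0.236). These 10 pairs of days share no libraries. The lesion effect differed between the 5 days for 3818 of the 5826 genes by a heterogeneity test on the implied standard errors (adjusted p under 0.1). Of the 129 genes named by rule, which were chosen largely for extreme values, 114 differed. Gap43, Sox11, Klf4, Tubb3 and Jun each differed between days in that test. Between days 2 and 3 no gene differed at an adjusted p under 0.1 in that test of pairs of days (557 at an unadjusted p under 0.05), and between days 3 and 5 the number was 3657.

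**Figure D4:**
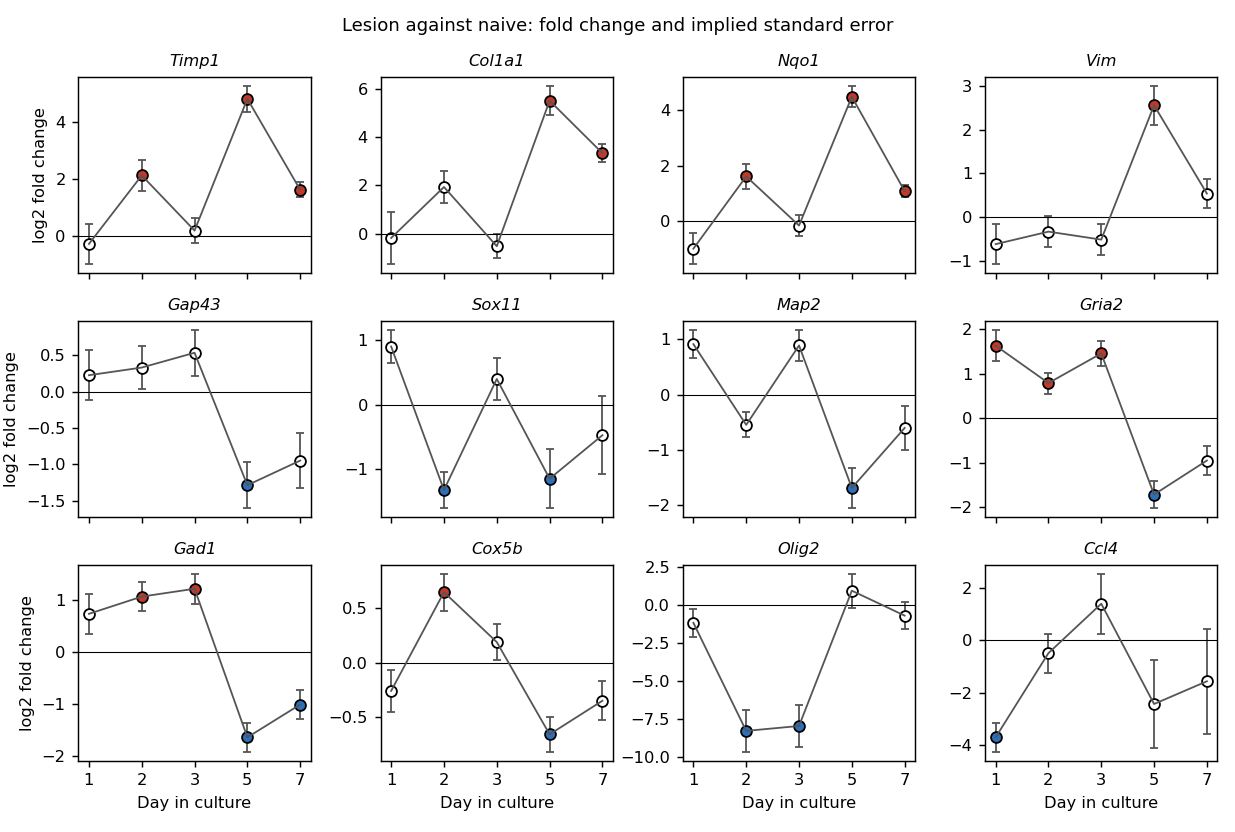
Log2 fold change of lesion against naive cultures for 12 genes at days 1, 2, 3, 5 and 7, with bars for the implied standard error; each panel has its own vertical scale. Red points rose, blue points fell and open points did not pass an adjusted p of 0.1; Gria2 goes from 1.46 at day 3 to -1.71 at day 5 and Timp1 from 0.20 to 4.81.

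Positions of the genes used as main examples, in the GRCm38 (mm10) build and the GENCODE annotation, where each is a protein-coding gene, were as follows. Col1a1 lies on chromosome 11 from 94936224 to 94953042 on the plus strand, and Timp1 on chromosome X from 20870166 to 20874735 on the plus strand. Gria2 lies on chromosome 3 from 80681450 to 80802835 on the minus strand, and Gap43 on chromosome 16 from 42248442 to 42340651 on the minus strand. Olig2 lies on chromosome 16 from 91225457 to 91228677 on the plus strand, and Ccl4 on chromosome 11 from 83662584 to 83664683 on the plus strand. Fold changes in the table refer to whole genes, not to single exons.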

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

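A test between days was planned only for given standard errors or t values, and the one used departs from that plan by resting on implied errors. Tests of list directions between days and those of cell share, of rank alone, of exchanged labels and of histone genes in this part were chosen after the results were seen. The test of a shared rank trend was written down before its result.

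A difference between days of the same lesion contrast is what singled out the results here. For 3818 genes the lesion effect differed between the 5 days by the heterogeneity test. Among the genes fixed in advance, the adjusted p of that test was 0.000582 for Sox11, 0.00777 for Gap43, 0.0307 for Tubb3, 0.0348 for Klf4 and 0.0908 for Jun.

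Directions of list members were compared between days by Fisher's exact test. It counts the changed members of the 2 days as independent and does not follow the same genes from day to day. Its null is an unchanged share of risen members. That share also moved among all changed genes, from 14.4% at day 1, 31.7% at day 2 and 36.2% at day 3 to 53.3% at day 5 and 75.9% at day 7, so a difference here need not be particular to the list. Of the lists and days compared here, the direction test against the other changed genes of the day passed only at day 1 for cytoskeletal genes, at day 2 for oxidative phosphorylation, at day 7 for extracellular matrix, and at day 5 for these 3 lists and for the cell cycle and pan-neuronal, synaptic, GABAergic, reactive astrocyte and interferon-stimulated genes. Between days 2 and 5, the changed members of the following lists went from mostly fallen to mostly risen. The adjusted p was 6.44e-06 for the cell cycle (7 fallen at day 2, 27 risen at day 5), 0.000154 for extracellular matrix, 0.00558 for endothelial markers (9 fallen, then 5 risen) and for interferon-stimulated genes, 0.0142 for the unfolded protein response and 0.0456 for cytokines. Risen members at day 5 were not over-represented against all genes tested for 3 of these lists (Fisher's exact test). They were endothelial markers (5 against 2.55 expected, adjusted p = 0.553), cytokines (8 against 4.34, 0.312) and interferon-stimulated genes (9 against 3.96, 0.0855). The endothelial genes named above as fallen did not pass the threshold at day 5: Cldn5 (1.16), Kdr (-0.42), Flt1 (-0.09) and Slco1a4 (1.67) in the authors' deposited table. Oxidative phosphorylation went against the shift of all changed genes, with 12 risen at day 2 and 13 fallen at day 5 (adjusted p = 6.44e-06). Changed genes ranked 1 to 1000, such as Cox5b of this list (rank 854), also shifted towards falling. Of those, 75 rose and 92 fell at day 2, and 119 rose and 303 fell at day 5. In the direction test matched on expression rank, the list passed at day 2 (adjusted p = 0.000563) but not at day 5 (0.0782). Pan-neuronal markers (4 risen and 3 fallen at day 2, 14 fallen at day 5) and synaptic genes (2 risen and 1 fallen, then 23 fallen) had a smaller share of risen members at day 5, with an adjusted p of 0.023 and 0.0309. From day 1 to day 5 the direction of changed members differed for reactive astrocyte genes, cytokines and interferon-stimulated genes (adjusted p = 0.00852 each). It also differed, from risen to fallen, for cytoskeletal genes (0.0429). Of the genes named as fallen at day 1, Ccl4 (-2.43), Ccl5 (-0.69), Il1b (-0.61) and Cxcl2 (-3.92) did not rise at day 5 in the authors' deposited table. Cxcl2 fell again, while Oasl1 (4.23) and Ifit3 (4.85) rose. Cytoskeletal genes also differed between day 1 and day 2 (adjusted p = 0.00997). Between days 3 and 5, GABAergic markers went from 3 risen to 1 risen and 15 fallen (adjusted p = 0.0184) and endothelial markers from 5 fallen to 5 risen (0.028). Day 7 differed from day 2 for extracellular matrix (adjusted p = 0.000114), the cell cycle (0.00558), axon guidance (0.00852) and growth-restraining factors (0.028), from day 1 for cytokines (0.0143), and from day 5 for axon guidance (0.0224).

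Fold changes at day 5 ran against those of days 1 and 3. If the other days agreed among themselves, an exchange of the lesion and naive labels at day 5 alone would make day 5, with its sign turned, correlate positively with them. With day 7 the value was -0.289. Day 7 itself, however, correlated with days 1, 2 and 3 at -0.0164, -0.138 and -0.142. It therefore gives no reference for the sign, and the test cannot decide on an exchange at day 5. A trend with expression rank shared by the days does not account for the whole pattern, since the correlation with day 1 was -0.295 after that trend was taken out (-0.236 with day 3). An exchange at day 5 alone or at both days 5 and 7 remains open, as does a change of the lesion effect itself with time in culture. No values per library were used that could separate them.

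Pan-neuronal and synaptic genes, though not glutamatergic cortical neuron markers (2 rose, 3 fell), fell at day 5 while matrix, cell cycle and mesenchymal genes rose. A lower share of neurons with all other cell types in proportion would raise the other markers alike. Medians of 7 marker lists spread over 4.42 log2 units (permutation test with 100000 draws, p = 0.00611). They ran from -0.90 for oligodendrocyte precursors to 3.51 for mural, fibroblast and meningeal markers. A first run with fewer draws fell on the same side of 0.05. The medians cover only members past the threshold at some day, and the lists differed in median rank, from 4781 to 16159. Oligodendrocyte members had passed at day 2 (10 fell) and mural, fibroblast and meningeal members mostly at day 5 (14 of 16 rose). The threshold can thus set part of the spread, and the test cannot decide on a lower neuron share. Over whole lists, 14 of 20 mural, fibroblast and meningeal markers and 0 of 24 oligodendrocyte markers rose at day 5. Expression rank alone is argued against for the 5 lists of this pattern (pan-neuronal, synaptic, extracellular matrix, cell cycle, and mural, fibroblast and meningeal). Their largest adjusted p in the direction test matched on rank was 0.0256. Cytoskeletal (0.714), interferon-stimulated (0.134) and oxidative phosphorylation genes (0.0782), which passed without matching at day 5, did not pass with it. As hypotheses, a larger share of dividing mesenchymal or glial cells in lesion cultures, or changed expression within cells, may account for the pattern. Cell cycle genes gave 27 risen of 30 at day 5, with none fallen. Replication-dependent histone genes, which dividing cells use, gave 1 risen and 6 fallen (direction test, adjusted p = 0.13, and 0.00998 matched on expression rank). How well the libraries captured histone transcripts is unknown here, so these values do not decide on cell division. Counts of dividing cells by type in these cultures would separate the hypotheses, which these bulk comparisons do not.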

How the results depend on the processing

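Tests matched on expression rank, over-representation, the restriction to ranks up to 9542, the removal of the rank trend and other forms of the implied errors were chosen after the results were seen; the other alternatives were planned. The count of genes differing between days (3818) stayed within 1.5 times under its alternatives (2969 at an adjusted p under 0.05, 4011 with normal errors, 3648 at 19 degrees of freedom). Counts at a day fell with a stricter threshold, by construction: an adjusted p under 0.05 gave 59, 511, 59, 2872 and 325 genes at days 1, 2, 3, 5 and 7, and one under 0.01 gave 17, 44, 15, 1098 and 76. An unadjusted p under 0.001 gave 440 at day 2, 1346 at day 5 and 354 at day 7, and a log2 fold change beyond 1 gave 748 at day 2. Only genes ranked up to 9542, fewer genes by construction, gave 154 at day 3 (98 rose, against 102 of 282 in all), 2853 at day 5 (947 rose, 1906 fell) and 430 at day 7. Without the lowest ranks and adjusted again, 1627 genes rose and 2121 fell at day 5. Genes changed in the same direction at 2 or more days numbered 698, with 264 at an adjusted p under 0.05, and 2211 where the other day needed an unadjusted p under 0.05. Lists past the direction test numbered 11 of the 17 without genes that another list holds; over-representation passed for 50 list and day pairs. Matching on rank passed for 15 pairs, 12 of the 17 and 3 others, and the restriction by rank for 21, 14 of the 17 and 7 others. Of the named values 101 also passed an adjusted p under 0.05 and 22 did not. Correlations near 0 changed sign: among genes past the threshold at either day, days 1 and 2 went from -0.109 to 0.0426 and days 1 and 7 from -0.0164 to 0.0935, and days 2 and 5 went from 0.0287 to -0.00855 (Spearman) and -0.0421 (rank trend taken out). Among genes ranked up to 9542, days 1 and 2 gave 0.0146 and days 2 and 5 -0.127. Among genes past the threshold, days 1 and 3 gave 0.176, days 2 and 3 0.866 and days 3 and 7 -0.0387. With the rank trend taken out, days 1 and 3 gave 0.159, days 1 and 5 -0.295, days 2 and 3 0.794 and days 3 and 5 -0.236, and Spearman's rho for days 2 and 3 was 0.526; the cause was not tested.

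No paired analysis was possible because the table holds no values per sample. For the same reason a block for the replicate number, leaving out each library, other scalings, a fit of only the groups compared and counts over other splits of the samples were not run. An adjustment over all 5 days together and the camera tests of lists were not run because the table holds only genes past the threshold, and changes over days within naive cultures were not analysed here. Depth is unknown, so no limit of detection is given.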

Other observations

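The families in this part and the genes named in it were chosen after the results were seen, as was the depth test; the tests of background reads and of length and GC content were written down before their results.

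Gene families defined by their symbols gave a further view of day 5. Of 23 collagen genes listed, 22 rose and none fell (Fisher's exact test of direction, adjusted p = 1.71e-05), as did 11 of 13 integrin genes (0.00841) and 9 of 10 T-box, Twist, Prrx and related mesenchymal regulators (0.0196). Small nucleolar RNA genes fell in 9 of 14 cases with none risen (adjusted p = 0.00841), and zinc finger genes of the Zfp series gave 40 fallen and 10 risen of 70 (2.55e-05). It is unknown here how well the libraries captured small nucleolar RNAs, so their counts need not reflect levels of the mature RNAs. Sodium and calcium channel genes gave 10 fallen and 1 risen of 14 (0.0196), and replication-dependent histone genes 6 fallen and 1 risen of 13 (0.13). These are from 35 tests; matched on expression rank, the adjusted p was 6.34e-06 for collagens, 0.0123 for integrins, 4.4e-12 for small nucleolar RNAs 4.47e-05 for zinc finger genes and 0.00998 for histone genes, against 0.151 for mesenchymal regulators and 0.0521 for the channels.

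Red cell genes, which neurons are not the main source of, fell in 3 of 8 cases at day 2 and rose in 5 of 8 at day 5 (over-representation, adjusted p = 0.027 and 0.0126), but direction did not differ from the other changed genes (adjusted p = 0.768 and 0.174, and 1 and 0.801 matched on expression rank). Hba-a1, an alpha globin gene, had log2 fold changes of -5.72 (standard error 1.33) and 5.70 (standard error 1.42) in the authors' deposited table. Hba-a1 has a near-identical copy, so its own share of the reads is uncertain. The growth factor genes Fgf2 and Bdnf of the regeneration list rose at day 5, by 5.54 (standard error 1.09) and 4.09 (standard error 1.13) in the authors' deposited table. Chromatin regulators gave 11 fallen and 3 risen of 25 at day 5 (over-representation of fallen genes, adjusted p = 0.000548), but direction did not differ from the other changed genes (adjusted p = 0.111, and 0.719 matched on expression rank). None of the 15 mitochondrially encoded genes is among the 5826 genes.

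Among the 5826 genes, weakly expressed ones rose and highly expressed ones fell at day 5 (Spearman's rho of fold change with rank 0.495). Only genes past the threshold at 1 or more days are included, 4575 of them at day 5, and this choice can set part of the trend. Gene length and GC content do not carry this trend. The correlation was 0.487 with both taken out, against 0.496 before over the same 5585 genes. Of neuronal genes ranked beyond 9542 and changed at day 5, 3 rose and 6 fell, against 1488 and 225 of the others (Fisher's exact test, p = 0.000324). That comparison was not matched on rank, and the share of risen genes also climbed with rank beyond 9542. It therefore cannot decide on depth as the sole cause. Background reads in the lesion libraries of day 5 remain a candidate explanation: of 30 chemosensory receptor genes in the table, which cortical cells have little known use for, 93.3% rose at day 5, against 88.5% of the other genes from rank 15865 on (Fisher's exact test, p = 0.563). By the criterion written down before, a share no lower than that of the others leaves this explanation open; a first reading of the same test had asked for a p under 0.05 and called it undecided, and it was brought back to the written criterion after the result was seen. The table holds only genes past the threshold, so receptor genes that did not move cannot be counted. Genes of these ranks are in it mostly for rising at day 5 (28 of 30 receptor genes and 569 of 643 others). Both shares were therefore nearly fixed in advance, and their comparison cannot decide on background reads. A contribution of depth or of few reads per gene to the pattern may remain.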
